A study of Homo sapiens with 12 samples.

How the data were processed

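RNA was sequenced from SEM-K2 cells, an established pro-B acute leukemia line with the MLL-AF4 fusion. The cells carried a doxycycline-inducible (Tet-On-Tight) vector that was empty (control line) or held HDAC7 (HDAC7 line). Each line was untreated or given doxycycline at 1 µg/ml for 48 h, which makes 4 groups of 3 libraries, 12 in all. Each library has a deposited table of 57736 Ensembl gene identifiers with 1 value each, and no value column was left unused.

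The deposited values are treated as a score: per the file headers they are normalized counts on a natural scale, and all are whole numbers. The submitters' processing notes name TopHat2, Bowtie2 and DESeq without versions, and the builds hg19 and GRCh37. The counting tool, the annotation release and the treatment of reads shared between genes are not given in the sources used here. Size factors recomputed by the median of ratios lay between 1.0032 and 1.0058. Some low whole numbers were empty in single libraries, as in the third doxycycline-treated HDAC7 library, where 10 of the values 1 to 40 did not occur. The values were therefore taken as counts that had been scaled and then rounded. Totals of the deposited values ran from 217790146 to 237418983 per library, and these are totals after scaling. The sequencing depth before scaling was not estimated from the empty values, and no counting interval was computed.

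Gene symbols, gene types and the order of neighbouring genes came from the GENCODE v29 reference on GRCh38. Positions are not given, because the deposited values rest on another build. Of the identifiers, 39843 had a symbol and 33905 had a value above 0 in at least 1 library.

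The plan made before the data were examined (contrasts, samples, threshold, gene lists and the rule for naming genes) assumed raw counts and a count model. The unit did not allow that model, so limma 3.58.1 with statmod 1.5.0 in R 4.3.3 was used in its place on log2 of the value plus 1, with a variance trend and robust moderation. Genes were kept with a value of at least 10 in at least 3 libraries and a total of at least 15, which left 19538. All 12 libraries entered 1 fit of 4 group means with 8 residual degrees of freedom. Contrasts were the doxycycline effect in the HDAC7 line, the doxycycline effect in the control line, the difference of these effects between lines (interaction), and the line difference without and with doxycycline. Tests were 2-sided, adjusted by Benjamini-Hochberg over the genes of each comparison, and a gene was called at an adjusted p under 0.05. The study removed the genes that changed with doxycycline in the control line, so that subtraction was computed as well. Errors of log2 fold changes are standard errors (SE), and errors of values are standard deviations (SD) over 3 libraries.

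No source used here says whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries. Replicate numbers were checked by correlating residuals of libraries with the same number. In the control line these correlations were 0.111 to 0.413 between untreated and doxycycline libraries, and the numbers paired the samples. A block for replicate number left the count of called genes there at 0. That block gave each number the same effect in both lines, and a paired fit of the control line alone was not run.

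HDAC7 and MYC were followed in every comparison. Other named genes are, per comparison, up to 8 with the largest rise and 8 with the largest fall among called genes whose groups do not overlap and whose lowest library in the higher group has at least 1 CPM, computed from the deposited values and their total. Clone-based names, pseudogenes and unnamed identifiers were left out. For the interaction the groups compared for overlap were the doxycycline and untreated HDAC7 libraries. Of each gene list that passed its test or had at least 3 called members, up to 4 called members were named by smallest p, and a text may stop earlier in this order.

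There were 32 fixed gene lists with 767 entries, of which 30 had no identifier. The list of mitochondrially encoded genes could not be tested because none of its 13 members was matched, which left 31 lists. Lists were tested with camera (limma) on the same log2 values with a preset correlation between genes of 0.01, and adjusted over the lists of each comparison. Beside this, camera was run with an estimated correlation, and fry tested whether the members moved on balance 1 way. Members were also counted with adjustment over the list alone.

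The method was tested on simulated data with 200 changed genes among 19107. Noise was drawn independently for each gene and library, without structure by replicate number, so the shares and false calls hold for such data only. For the doxycycline effect in the HDAC7 line it recovered 25 of 62 genes changed 1.5-fold (40.3%) and 55 of 71 changed 2-fold (77.5%), with 5 false calls. For the interaction it recovered 16 of 62 (25.8%) and 49 of 71 (69%), with 8 false calls. The unchanged control comparison gave 0 calls. Alternatives covered scaling, filter, threshold, pseudocount, replicate block, samples used and the weighting of voom, and each library was left out in turn. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.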

Results

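The transcriptome of SEM-K2 was measured by RNA sequencing in a control line with an empty inducible vector and in a line in which doxycycline induces HDAC7, a class IIa histone deacetylase that represses transcription in B-cell progenitors. Each line was measured untreated and after doxycycline (1 µg/ml, 48 h), with 3 libraries in each of the 4 groups. The deposited normalized counts summed to between 217790146 and 237418983 per library. The first principal component held 33.5% of the variance and the second 14.5%.

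HDAC7 (ENSG00000061273) was the gene under experimental control. Its normalized count was 28160 ± 1220 (SD, n = 3) in the untreated control line and 27370 ± 1020 (SD, n = 3) in the control line with doxycycline. In the HDAC7 line it was 42650 ± 700 (SD, n = 3) untreated and 788500 ± 39200 (SD, n = 3) with doxycycline, an 18.5-fold rise (log2 fold change 4.21 ± 0.06 SE, limma adjusted p = 2.57e-13). Doxycycline left HDAC7 without a detected change in the control line (-0.04, adjusted p = 1). Without doxycycline the HDAC7 line held 1.52-fold more HDAC7 than the control line (0.60 ± 0.06 SE, adjusted p = 5.96e-05), and with doxycycline 28.8-fold more (4.85, adjusted p = 4.54e-14). All 3 libraries of the higher group lay above all 3 of the lower one in each of these called differences. HDAC7 took at most 0.3679% of a library's total. MYC, a growth regulator, was not called in any comparison: its log2 fold change after doxycycline was -0.17 ± 0.14 SE in the HDAC7 line (adjusted p = 0.604) and -0.09 in the control line (adjusted p = 1), and the line differences were 0.38 without doxycycline (adjusted p = 0.151) and 0.29 with it (adjusted p = 0.195).

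**Figure D1:**
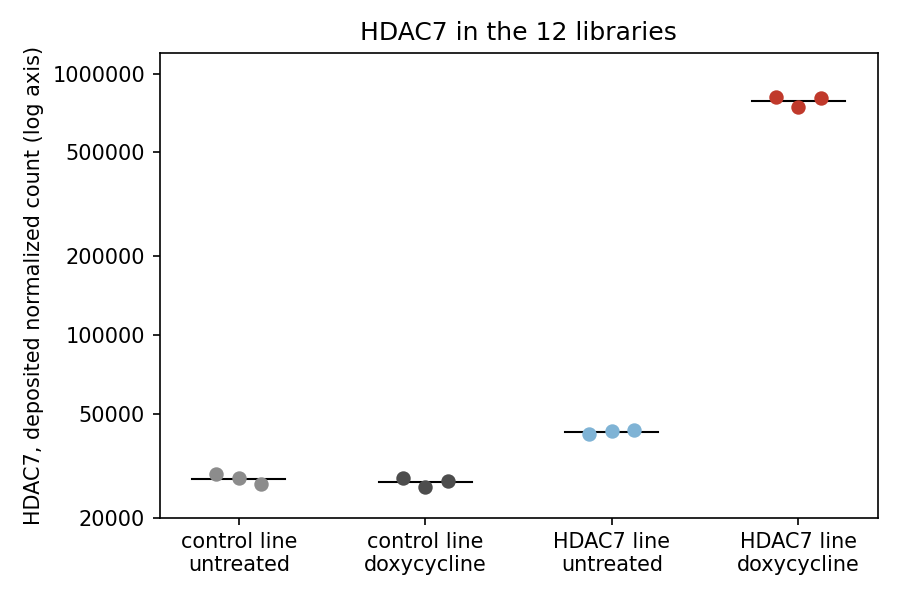
Normalized count of HDAC7 in each of the 12 libraries (points, log axis) with group means (bars), by line and treatment. The 3 doxycycline-treated HDAC7 libraries lie between 743808 and 816713, and the untreated HDAC7 libraries between 41919 and 43314.

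The first comparison asked what changed when HDAC7 was induced in the leukemic cells. More genes rose than fell. The largest rises among the named genes were those of a coagulation factor, a lysophospholipase, a vascular growth factor receptor and a water channel. Called were 794 of 19538 genes, with 590 rises and 204 falls (74.3% rises), and 278 rises and 24 falls were at least 2-fold. Protein-coding genes made up 714 of the 794. F13A1 (ENSG00000124491), the catalytic subunit of coagulation factor XIII, was listed at 0 in all control libraries and at 0, 3 and 0 in the untreated HDAC7 libraries, and at 478, 366 and 294 after doxycycline (adjusted p = 7.23e-06). ENPP2 (ENSG00000136960), which encodes the secreted lysophospholipase autotaxin, went from 127.3 to 5138 on average (log2 fold change 5.33 ± 0.52 SE, adjusted p = 8.9e-05). KDR, the receptor VEGFR2, rose by 5.24 ± 0.48 SE (adjusted p = 5.93e-05) from a mean of 14 to 543.3. AQP1, a water channel, rose by 5.18 ± 0.47 SE (adjusted p = 5.71e-05) from 14.33 to 545.7. Rises of 3.76 to 3.95 were seen in FILIP1L, AURKC, a kinase of meiosis, and the secreted glycoprotein gene OLFML3 (adjusted p from 2.03e-05 to 0.000734). The largest falls were smaller: CLCN4, a chloride-proton exchanger, fell from 510 to 166.3 (-1.61 ± 0.29 SE, adjusted p = 0.00759) and UPB1, an enzyme of pyrimidine breakdown, from 369 to 134.7 (-1.40 ± 0.24 SE, adjusted p = 0.00591). In each of these genes the 3 doxycycline values lay on 1 side of the 3 untreated values, as the rule for naming them required. CLCN4 and UPB1 were not called in the interaction. In the control line CLCN4 held 1478, 814 and 949 untreated and 1155, 897 and 787 with doxycycline. UPB1 held 1035, 644 and 622 there untreated and 688, 501 and 572 with doxycycline. The count of 794 rested on few libraries: it was 336 without the third, 385 without the first and 430 without the second doxycycline-treated HDAC7 library. It was 465 and 493 without the first and the second untreated HDAC7 library. Without 1 of the control-line libraries, which share the fit, it was 655 to 1046. With libraries scaled to equal totals 917 genes were called and the share of rises was 86.6%, and among called genes with a control-line mean of at least 20 CPM it was 54.2%. A replicate block gave 1799 genes (1021 rises, 778 falls), and a fit of this line alone gave 1632 (1031 rises, 601 falls).

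**Figure D2:**
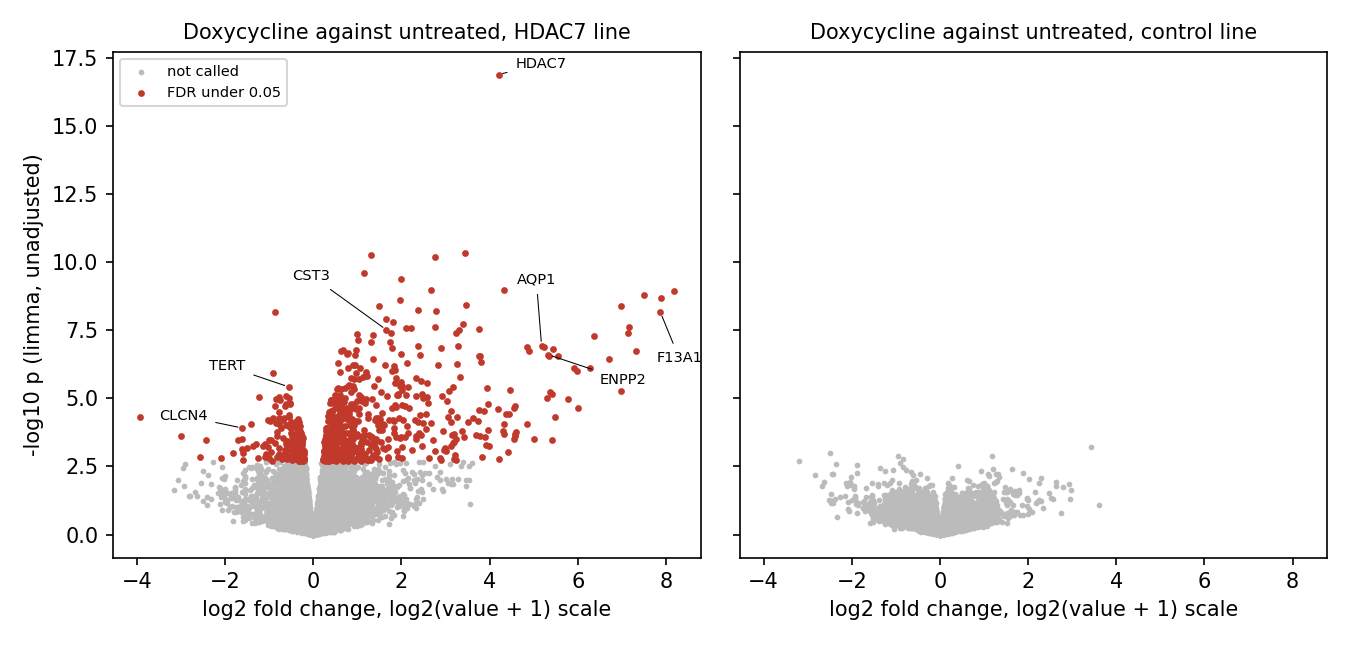
Log2 fold change (on log2 of the value plus 1) against -log10 of the unadjusted limma p for doxycycline in the HDAC7 line (left) and the control line (right), with genes at an adjusted p under 0.05 in red. The HDAC7 line has 794 red genes and the control line 0.

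Groups of genes moved with HDAC7 induction as well. Some markers of myeloid cells and of T and NK cells rose in these B-lineage cells, and some genes of DNA replication fell. Of 31 gene lists, 10 passed camera with the preset correlation, 3 upward and 7 downward, and none passed with an estimated correlation in this or any other comparison. Of 26 listed myeloid genes 16 were measured, and 4 were called upward and 0 downward (median 0.38, camera adjusted p = 8.47e-05, adjusted p = 0.0741 with an estimated correlation), and 6 rose when adjusted over the list alone. CST3, a cysteine protease inhibitor, rose from 493.7 to 1559 (1.66 ± 0.14 SE, adjusted p = 2.14e-05). CD68, a lysosomal glycoprotein, rose from 992 to 2281 (1.20 ± 0.13 SE, adjusted p = 0.000257), and ITGAM, the integrin chain CD11b, from 110.7 to 455 (2.12 ± 0.29 SE, adjusted p = 0.00119). ITGAM started lower in the HDAC7 line than in the control line, which held 257, 175 and 234 untreated and 317, 212 and 225 with doxycycline. Of 26 listed T-cell and NK-cell genes 10 were measured, and 2 were called upward and 0 downward (median 0.39, camera adjusted p = 0.00393, adjusted p = 0.48 with an estimated correlation), and 5 rose and 1 fell when adjusted over the list alone. LAT, an adaptor of antigen receptor signalling, rose from 1413 to 3629 (1.36 ± 0.11 SE, adjusted p = 2.78e-05), and CD3E was listed at 0 in the untreated HDAC7 libraries and at 24, 25 and 11 after doxycycline (adjusted p = 0.00929). CD3E lay near the floor, the doxycycline-treated control libraries held 0, 7 and 0, and it was not called in the interaction. The median of this list was 0.22 without the third untreated and 0.25 without the second doxycycline-treated HDAC7 library. Of 30 published core target genes of MLL-AF4, 4 rose and 2 fell (median 0.13, camera adjusted p = 0.0231, adjusted p = 0.48 with an estimated correlation), and 9 rose and 3 fell when adjusted over the list alone. The call of this list was lost without the second doxycycline-treated HDAC7 library (adjusted p = 0.0731).

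Among the lists that fell, DNA replication genes had 10 of 30 members called downward and 0 upward (median -0.23, camera adjusted p = 2.51e-17, adjusted p = 0.0741 with an estimated correlation), and 25 fell when adjusted over the list alone. Its changes were small: MCM3, a subunit of the replicative helicase, fell by 0.25 ± 0.05 SE (adjusted p = 0.0122). The call of MCM3 was lost without any 1 of the HDAC7-line libraries except the third untreated one (adjusted p up to 0.0623). Target genes of ATF4, the transcription factor of the amino acid response, had 1 of 28 members called downward and 0 upward (median -0.79, camera adjusted p = 2.32e-12, adjusted p = 0.737 with an estimated correlation), and 22 fell when adjusted over the list alone. The called member, PYCR1 of proline synthesis, fell by a small margin (-0.58 ± 0.14 SE, adjusted p = 0.0399), and its call was lost without any 1 of the HDAC7-line libraries except the second untreated one (adjusted p up to 0.146). Among 28 MYC target genes 1 was called downward and 0 upward (median -0.10, camera adjusted p = 0.0113, adjusted p = 0.737 with an estimated correlation), and 1 fell when adjusted over the list alone. That gene was TERT, the catalytic subunit of telomerase, which fell from 7019 to 4766 (-0.56 ± 0.07 SE, adjusted p = 0.000704). Mitosis genes had 0 of 26 members called, also when adjusted over the list alone (median -0.08, camera adjusted p = 0.0113, adjusted p = 0.737 with an estimated correlation). The calls of the MYC target and mitosis lists were lost without the second untreated HDAC7 library (adjusted p = 0.168 for each) and with quantile normalization (0.2 and 0.362), and that of mitosis also with equal totals (0.0744). Nuclear-encoded oxidative phosphorylation genes and cytosolic ribosomal protein genes each had 0 of 30 members called, also when adjusted over the list alone (medians -0.12 and -0.13, camera adjusted p = 2.46e-06 and adjusted p = 0.737 with an estimated correlation for each), and quantile normalization ended the ribosomal protein call (0.418). Mitochondrial ribosome genes had 1 of 29 called downward and 0 upward (median -0.13, camera adjusted p = 9.24e-06, adjusted p = 0.737 with an estimated correlation), and 7 fell when adjusted over the list alone. Without the first untreated HDAC7 library the medians were -0.47 for ATF4 targets, -0.16 for MYC targets and -0.064 for cytosolic ribosomal protein genes, and without the second untreated one -0.04 for MYC targets.

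The second comparison measured what doxycycline itself did in cells without inducible HDAC7. No gene was called there. limma gave 0 genes of 19538, with 284 at an unadjusted p under 0.05 against 977 expected by chance. Voom weighting and a replicate block also gave 0 (474 genes at an unadjusted p under 0.05 with the block). The block was shared by both lines, so its result is not that of a paired fit of the control line alone. With the libraries numbered 1 left out 1 gene was called. With the 8 residual degrees of freedom, the unadjusted 95% interval of a log2 fold change had a median width of 0.328 to either side. The moderation in limma adds 4.15 to 4.24 degrees of freedom, so the interval of the test used is somewhat narrower. The limit for a call is higher: in simulated data for the HDAC7 line 40.3% of 1.5-fold changes were called, so changes of that size can be missed. That share does not give the power of the control comparison. The simulated changes were in the HDAC7 line, and the simulated noise had no structure by replicate number. Among the lists, DNA replication genes were lower (median -0.08, 0 members called up and 0 down, also when adjusted over the list alone, camera adjusted p = 2.17e-08, adjusted p = 0.626 with an estimated correlation). The lists of mitosis genes (median 0.08, adjusted p = 1.55e-05), interferon-stimulated genes (0.09, adjusted p = 0.0137) and MHC class I antigen presentation genes (0.06, adjusted p = 0.0351) were higher, with 0 members called, also when adjusted over the list alone, and an adjusted p = 0.877 with an estimated correlation in each. Without the third untreated control library these 3 lists gave an adjusted p of 0.789, 0.077 and 0.211, and without the first doxycycline-treated control library 0.419, 0.288 and 0.668. Without the second untreated control library the interferon and MHC class I lists gave 0.662 and 0.518, and without the third doxycycline-treated control library the MHC class I list gave 0.0612. The medians of the mitosis, interferon and MHC class I lists were 0.15, 0.14 and 0.16 without the first untreated control library, and 0.011, 0.025 and 0.021 without the first doxycycline-treated one. Without the second untreated control library the interferon and MHC class I medians were 0.03 and 0.032, without the third the mitosis median was 0.005, and without the second doxycycline-treated control library the MHC class I median was 0.15. With the replicate block the list of MYC target genes was also called lower (median -0.05, adjusted p = 0.0185, adjusted p = 0.954 with an estimated correlation, 0 members called up and 0 down). Its median was -0.234 (adjusted p = 9.59e-09) without the first untreated and -0.225 (adjusted p = 3.74e-07) without the second doxycycline-treated control library. Lists that were not called with all libraries passed in the same direction in 22 cases when 1 was left out: 8 and 5 without the first and the second untreated control library, and 5 and 4 without the first and the second doxycycline-treated one. Passes in the opposite direction are not in this count, such as ATF4 target genes without the first untreated library (median 0.274, camera adjusted p = 0.000159). The fits with 1 library left out had no block, and each parts a pair of numbers. They cannot tell a doxycycline effect from a difference between numbers.

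The third comparison tested directly which genes responded to doxycycline differently in the HDAC7 line than in the control line. Most of these genes rose more in the HDAC7 line. The study's subtraction left all 794 genes (590 rises, 204 falls), since the control line had none to remove. The interaction called 164 genes, 158 upward and 6 downward, and 163 of them were also called in the HDAC7 line. F13A1 was again at the top (adjusted p = 0.000363), followed by ENPP2 (5.56 ± 0.74 SE, adjusted p = 0.00261), AQP1 (5.12 ± 0.67 SE, adjusted p = 0.00233) and KDR (4.85 ± 0.68 SE, adjusted p = 0.00405). HDAC7 itself differed by 4.25 ± 0.08 SE (adjusted p = 1.57e-11). The myeloid genes CST3 (1.38 ± 0.19 SE, adjusted p = 0.00372) and CD68 (1.21 ± 0.19 SE, adjusted p = 0.00841) and the adaptor LAT (1.26 ± 0.16 SE, adjusted p = 0.00232) were called too. Falls were led by GATM, an enzyme of creatine synthesis that went from 3207 to 1698 in the HDAC7 line (-0.94 ± 0.15 SE, adjusted p = 0.00841), and SNX22, a sorting nexin that went from 16170 to 8824 (-0.81 ± 0.09 SE, adjusted p = 0.000677). Without the first or the third doxycycline-treated HDAC7 library 68 genes were called, without the second 82, without the second untreated HDAC7 library 104, without the third untreated control library 107 and without the third doxycycline-treated control library 108. With a replicate block the interaction called 439 genes, 321 upward and 118 downward.

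Of the lists, 9 passed in the interaction with the preset correlation, and the myeloid genes were among them. Of the 16, 3 were called upward and 0 downward (median 0.39, camera adjusted p = 1.01e-05, adjusted p = 0.0846 with an estimated correlation), and 5 rose when adjusted over the list alone. T-cell and NK-cell genes had 1 of 10 called upward and 0 downward (median 0.32, adjusted p = 0.00142, adjusted p = 0.389 with an estimated correlation), and 4 rose when adjusted over the list alone. No member was called over all genes in the other 7, and 1 when adjusted over the list alone, an MLL-AF4 target that was lower. The MLL-AF4 target list as a whole was higher (median 0.13, adjusted p = 0.0154, adjusted p = 0.389 with an estimated correlation). Lower were DNA replication genes (-0.16, adjusted p = 9.02e-09, adjusted p = 0.307 with an estimated correlation), ATF4 target genes (-0.71, 2.64e-09 and 0.685), mitosis genes (-0.15, 8.25e-06 and 0.685), oxidative phosphorylation genes (-0.12, 6.59e-06 and 0.685), cytosolic ribosomal protein genes (-0.14, 5.93e-06 and 0.854, and 0.327 with quantile normalization) and mitochondrial ribosome genes (-0.12, 0.00012 and 0.854). The MLL-AF4 target call was lost without the first untreated control library (0.0659), the third doxycycline-treated control library (0.0919) or the second doxycycline-treated HDAC7 library (0.0599), and the mitochondrial ribosome call without the first untreated (0.247) or the second doxycycline-treated control library (0.0792). Several of these medians moved with 1 library. Without the first untreated control library they were -1.11 for ATF4 targets, -0.23 for mitosis, -0.066 for oxidative phosphorylation and -0.024 for the mitochondrial ribosome, and without the second untreated control library 0.087 for MLL-AF4 targets and -0.22 for the mitochondrial ribosome. Without the first doxycycline-treated control library they were 0.48 for T-cell and NK-cell genes, -0.098 for mitosis, -0.089 for cytosolic ribosomal protein genes and -0.21 for the mitochondrial ribosome, which without the second such library had -0.054. Without the first untreated HDAC7 library the ATF4 and cytosolic ribosomal protein medians were -0.42 and -0.071, without the second and the third the T-cell and NK-cell median was 0.49 and 0.17, and without the second doxycycline-treated HDAC7 library the MLL-AF4 median was 0.08.

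**Figure D3:**
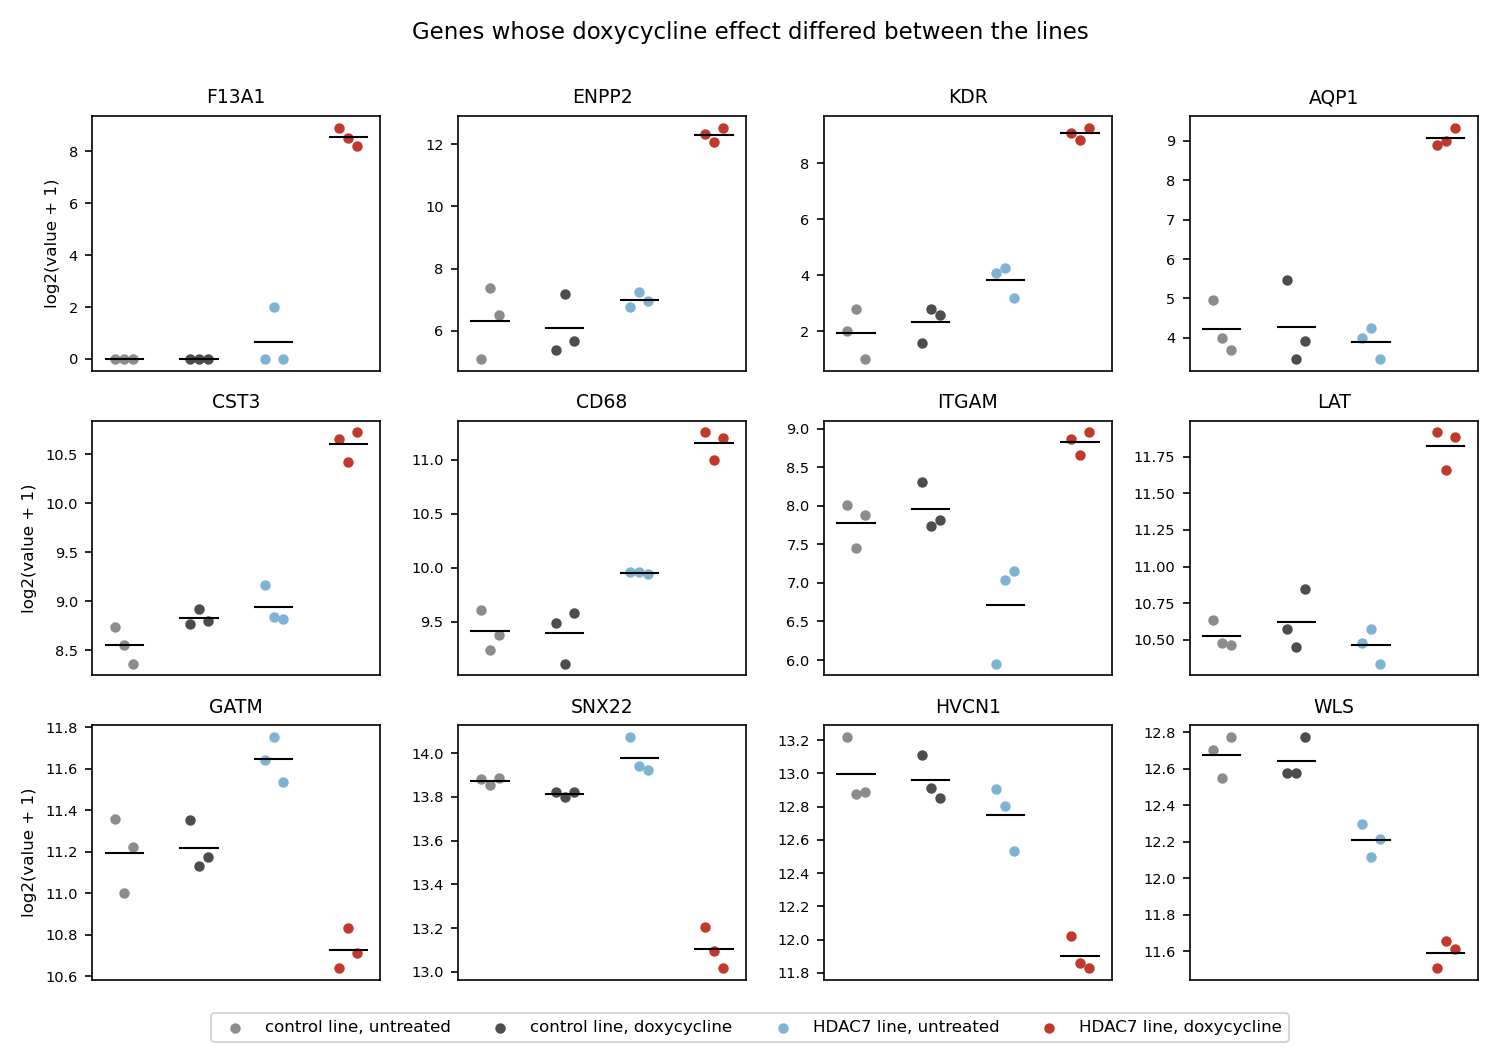
Log2 of the value plus 1 in each library (points) with group means (bars) for 12 genes whose doxycycline effect differed between the lines, coloured by line and treatment. In F13A1 the doxycycline-treated HDAC7 libraries held 478, 366 and 294 and the control libraries 0, while GATM, SNX22, HVCN1 and WLS fell.

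The fourth comparison asked whether the lines differed before induction. They did, and more genes were lower than higher in the HDAC7 line. Among the lower ones were the recombination genes RAG1 and RAG2 and the B-cell adaptor BLNK, although the lists of B-cell genes that hold them did not pass. Among the higher ones were the transcription factor RUNX2 and LIN28B, an RNA-binding protein of fetal hematopoiesis. Called were 1061 genes, 376 higher and 685 lower in the HDAC7 line, 99 and 229 of them at least 2-fold. MAP7D2, a microtubule-associated protein, was higher (339.7 against 1793, 2.46 ± 0.27 SE, adjusted p = 0.000186), as was LIN28B (133.3 against 469, 1.81 ± 0.17 SE, adjusted p = 5.96e-05). The phosphatase gene CPPED1 was listed at 746, 492 and 501 in the control line and at 1, 3 and 0 in the HDAC7 line (adjusted p = 7.51e-07). SLAMF8, a surface receptor of the SLAM family, averaged 703.7 against 16.67 (-5.34, adjusted p = 1.13e-05), TBX21, the transcription factor T-bet, 514.3 against 12.67 (-5.24, adjusted p = 0.000156) and the integrin chain ITGB8 869.7 against 38.33 (-4.50, adjusted p = 9.52e-07). In each of these genes the 3 libraries of 1 line lay on 1 side of the 3 of the other, as the rule for naming them required. The count was 592 without the second untreated HDAC7 library, 595 without the third untreated control library and 685 without the third untreated HDAC7 library.

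Lists of antigen presentation were lower in the untreated HDAC7 line with the preset correlation, not with an estimated one. MHC class II genes had 8 of 13 members called lower and 0 higher (median -0.76, camera adjusted p = 1.07e-11, adjusted p = 0.28 with an estimated correlation), and all 13 were lower when adjusted over the list alone. HLA-DPA1 differed by -0.73 ± 0.10 SE (adjusted p = 0.000874) and HLA-DQB1 by -1.17 ± 0.21 SE (adjusted p = 0.00605). Values of HLA and histone genes are uncertain, since these genes have close copies and how shared reads were counted is not given in the sources used here. MHC class I antigen presentation genes had 6 of 16 called lower and 0 higher (median -0.34, adjusted p = 8.23e-06, adjusted p = 0.28 with an estimated correlation), and 8 were lower when adjusted over the list alone. Leading them were NLRC5, the transactivator of class I genes (-0.74 ± 0.09 SE, adjusted p = 0.000319), and the peptide transporter TAP2 (-0.35 ± 0.05 SE, adjusted p = 0.00193). MLL-AF4 target genes had 9 of 30 higher and 2 lower (median 0.16, adjusted p = 1.12e-05, adjusted p = 0.0775 with an estimated correlation), and 13 and 2 when adjusted over the list alone. RUNX2 was higher (1.68 ± 0.11 SE, adjusted p = 4.25e-06), and TCF4, an E-protein transcription factor, was lower (-1.81 ± 0.13 SE, adjusted p = 7.49e-06). Replication-dependent histone genes had 3 of 10 higher and 0 lower (median 0.80, adjusted p = 1.12e-05, adjusted p = 0.0775 with an estimated correlation), and 8 when adjusted over the list alone. Mitosis genes had 3 of 26 lower and 0 higher (median -0.17, adjusted p = 0.000112, adjusted p = 0.85 with an estimated correlation, 3 lower when adjusted over the list alone), and adhesion and migration genes had 4 of 20 lower and 0 higher (median -0.08, adjusted p = 0.0221, adjusted p = 0.85 with an estimated correlation, 6 lower when adjusted over the list alone). Both calls were lost without the first untreated control library (0.105 and 0.242), and that of adhesion also without the third untreated HDAC7 library (0.0846). Without the first untreated control library the medians were -0.086 for mitosis and -0.018 for adhesion, and without the second -0.18 for adhesion. Pro-B and pre-B stage genes did not pass as a list (adjusted p = 0.133), with 2 of 18 higher and 5 lower: IKZF2, an Ikaros-family factor, was higher (1.40 ± 0.13 SE, adjusted p = 7.22e-05), and IRF8 (-0.56 ± 0.06 SE, adjusted p = 0.000198), RAG1 (-2.25 ± 0.28 SE, adjusted p = 0.000556) and RAG2 (-1.12 ± 0.15 SE, adjusted p = 0.000894) were lower. B-cell lineage genes did not pass either (adjusted p = 0.369), with 1 of 28 higher and 3 lower, BLNK at -2.85 ± 0.34 SE (adjusted p = 0.00034).

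The fifth comparison set the lines side by side under the same drug, so it holds the induction of HDAC7 together with any difference that the lines had before. It gave the most called genes of the 5: 2606, with 1290 higher and 1316 lower in the HDAC7 line, 491 and 321 of them at least 2-fold. A coagulation factor, a growth factor receptor, a lysophospholipase and a guidance cue led the rises. F13A1 was listed at 0 in the 3 control libraries. KDR averaged 4.333 against 543.3 (6.75 ± 0.48 SE, adjusted p = 3.1e-06), ENPP2 differed by 6.23 ± 0.52 SE (adjusted p = 1.02e-05), and NTN1, the guidance cue netrin-1, averaged 29.67 against 1247 (5.51 ± 0.39 SE, adjusted p = 2.74e-06). CPPED1 was listed at 604, 480 and 479 in the control line and at 0 in all 3 HDAC7 libraries. TBX21 averaged 497.3 against 8.333 (-6.15 ± 0.56 SE, adjusted p = 1.96e-05), and SLAMF8 differed by -5.48 (adjusted p = 5.02e-06). The count was 1536, 1580 and 1667 without the second, the first and the third doxycycline-treated HDAC7 library, and 1586 without the third doxycycline-treated control library.

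Mitosis genes were lower as a list in the doxycycline-treated HDAC7 line. Of 26, 13 were called lower and 0 higher (median -0.32, camera adjusted p = 1.8e-10, adjusted p = 0.396 with an estimated correlation), and 22 when adjusted over the list alone. PTTG1, the separase inhibitor securin, differed by -0.56 ± 0.06 SE (adjusted p = 0.000106). MLL-AF4 target genes had 18 of 30 higher and 5 lower (median 0.37, adjusted p = 2.46e-06, adjusted p = 0.0558 with an estimated correlation), and 20 and 5 when adjusted over the list alone. Histone genes had 5 of 10 higher and 0 lower (median 0.88, adjusted p = 2.46e-06, adjusted p = 0.0558 with an estimated correlation), and 8 when adjusted over the list alone. MHC class II genes had 1 of 13 higher and 8 lower (median -0.72, adjusted p = 2.31e-05, adjusted p = 0.574 with an estimated correlation, 1 and 9 when adjusted over the list alone), and MHC class I genes had 0 of 16 higher and 8 lower (median -0.41, adjusted p = 2.31e-05, adjusted p = 0.263 with an estimated correlation, 9 lower when adjusted over the list alone). T-cell and NK-cell genes had 5 of 10 higher and 0 lower (median 0.50, adjusted p = 0.000562, adjusted p = 0.263 with an estimated correlation), and 6 when adjusted over the list alone, with GATA3, a T-cell transcription factor, after LAT at 1.19 ± 0.14 SE. Myeloid genes had 3 of 16 higher and 0 lower (median 0.22, adjusted p = 0.0105, adjusted p = 0.263 with an estimated correlation), and 6 higher and 1 lower when adjusted over the list alone. LYZ, lysozyme, came after CD68 and CST3 (3.64 ± 0.44 SE, adjusted p = 0.000167). DNA replication genes had 6 of 30 lower and 0 higher (median -0.15, adjusted p = 0.000193, adjusted p = 0.396 with an estimated correlation), and 9 lower when adjusted over the list alone. ATF4 target genes had 2 of 28 lower and 0 higher (median -0.63, adjusted p = 0.000276, adjusted p = 0.823 with an estimated correlation), and 2 when adjusted over the list alone. Oxidative phosphorylation genes had 5 of 30 lower (median -0.09, adjusted p = 0.00124, adjusted p = 0.823 with an estimated correlation), mitochondrial ribosome genes 3 of 29 (-0.06, 0.0299 and 0.902) and cytosolic ribosomal protein genes 0 of 30 (-0.08, 0.0331 and 0.928), and in each 0 members were called higher and the counts were the same when adjusted over the list alone. Without the second doxycycline-treated control library the first of these lists gave 0.0663 and the second 0.622, without the first doxycycline-treated HDAC7 library the second gave 0.0853 and the third 0.0503, and without the first doxycycline-treated control or the second doxycycline-treated HDAC7 library the third gave 0.59 and 0.222. Quantile normalization also ended the calls of both ribosome lists (0.103 and 0.454), and equal totals that of the cytosolic one (0.0659). Without the first doxycycline-treated control library the medians were -0.31 for ATF4 targets, -0.20 for the mitochondrial and -0.023 for the cytosolic ribosome. Without the second they were 0.89 for T-cell and NK-cell genes, 0.38 for myeloid genes, -0.039 for oxidative phosphorylation, -0.038 for the mitochondrial and -0.12 for the cytosolic ribosome. Without the second doxycycline-treated HDAC7 library the cytosolic ribosome had -0.054, and without the third the mitochondrial ribosome had -0.11.

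**Figure D4:**
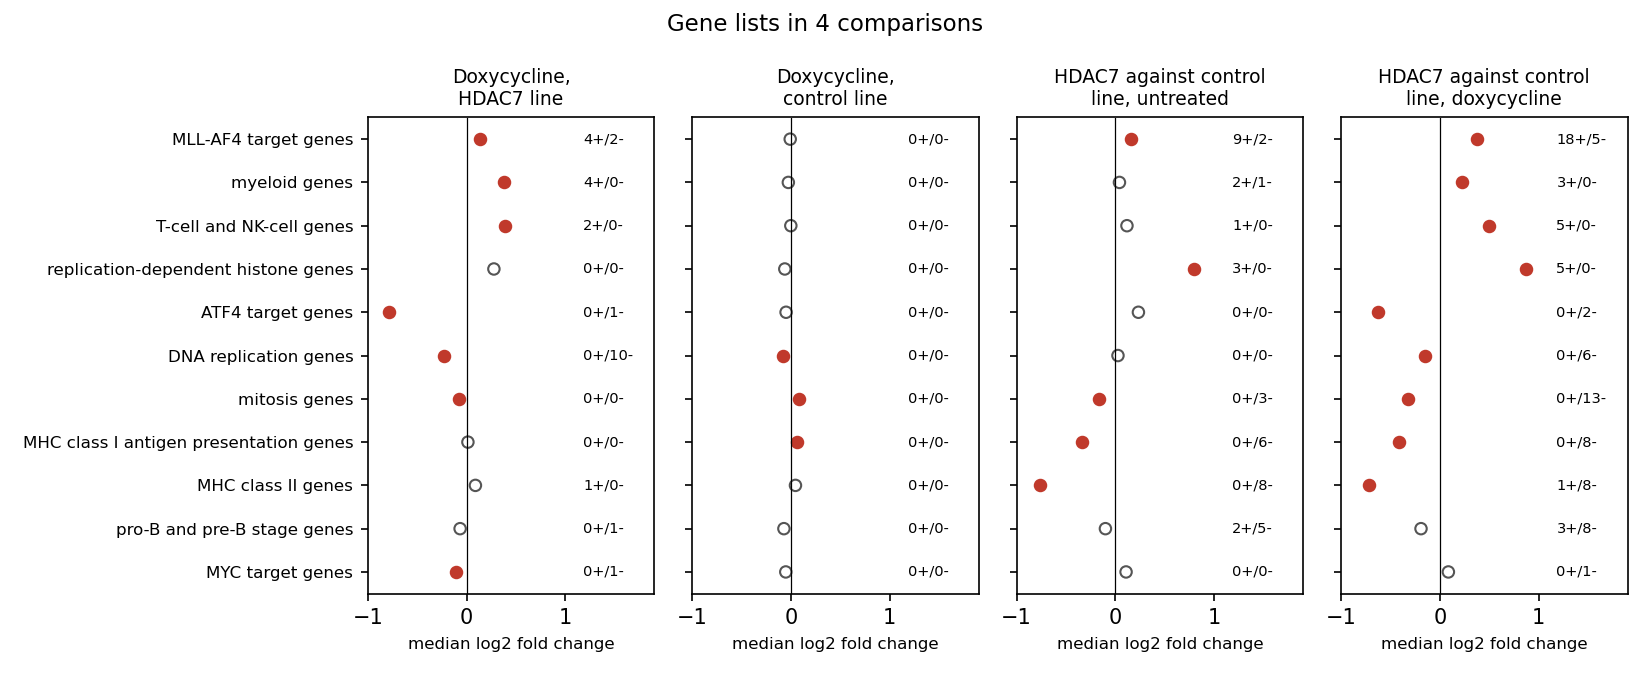
Median log2 fold change of the members of 11 gene lists in 4 comparisons, filled red where camera with the preset correlation gave an adjusted p under 0.05 and open otherwise, with the members called up (+) and down (-) written beside each point. MHC class II genes lie at -0.76 without and -0.72 with doxycycline between the lines, and DNA replication genes at -0.23 after doxycycline in the HDAC7 line; no call holds with an estimated correlation, and mitosis and MYC targets in the HDAC7 line lose theirs with quantile normalization.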

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

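Of the tests in this part, those of abundance, of the replicate block and of the ATF4 target list were chosen after the results they concern were seen.

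The interaction test marked 164 genes whose doxycycline effect differed between the lines. HDAC7 itself was among them (4.25). The other named genes with a larger rise in the HDAC7 line were F13A1 (7.88), ENPP2 (5.56), AQP1 (5.12), KDR (4.85), SIGLEC15 (4.39), SERPINF2 (4.09) and OLFML3 (4.08), and of the myeloid and T-cell lists ITGAM (1.94), CST3 (1.38), LAT (1.26) and CD68 (1.21). Lower were GATM (-0.94), SNX22 (-0.81), HVCN1 (-0.81) and WLS (-0.59). The estimate of F13A1 depends on the pseudocount (5.13 with 10 and 8.6 with 0.5 in place of 1), because its control values are 0. The calls of some of these genes did not survive the loss of 1 library. SIGLEC15 lost its call in 9 of 12 cases (adjusted p up to 0.107), all but those without the first untreated control, the second doxycycline-treated control and the second untreated HDAC7 library. HVCN1 lost it in 10 of 12 (up to 0.177), all but those without the first untreated control and the third untreated HDAC7 library. WLS lost it in 12 of 12 (0.0502 to 0.158). ITGAM lost it in 8 of 12 (up to 0.184), which were those without the first or the third untreated control, the second or the third doxycycline-treated control, the second untreated HDAC7 and any doxycycline-treated HDAC7 library.

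Other groupings of the same libraries were tried to see how many genes they call. With 6 libraries in groups of 3 there are 10 splits, too few for a share under 0.05. The real split gave 794 genes in the HDAC7 line and the highest other split 0, and 1 of the 10 was as large. Between the lines the real splits gave 1061 genes without doxycycline (highest other 0, 1 of 10 as large) and 2606 with it (highest other 1, 1 of 10 as large). In the other splits of these comparisons the real difference enters the spread and keeps calls low. Their low counts therefore do not tell whether the real calls could arise by chance. In the control line all 10 splits were as large as the real value of 0, and the highest gave 3551. That split set the first untreated and the first and the third doxycycline-treated libraries against the rest, so it kept both libraries numbered 1 together, and it points to a structure of the samples by replicate number in the control line. The 4 splits that part all pairs, as the real one does, gave 0 genes at most. For the interaction 12 of 100 drawn splits gave at least as many genes as the real 164, itself included, and the highest other gave 2859. By the rule set beforehand this share leaves chance open. All 11 others kept the real split of the HDAC7-line libraries, and with it the real effect, so this share does not tell whether chance is excluded. They were all of the draws with that split, so the real control labels gave no more genes than any of these redraws. Of the 88 draws with another split of those libraries, 0 gave as many genes. Parting the draws in this way was not in the rule, and in those draws the real effect enters the spread.

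Rises outnumbered falls among the genes called in the HDAC7 line, at 74.3%, and the called rises started from a median value of 494 and the falls from 6920, against 1300 over all genes tested. The scaling is argued against as the whole cause, since the lowest share under 3 other scalings was 70.5%, whereas a floor at low abundance that lets genes rise but not fall stays open: rises were 61.8% of called genes with a control-line mean of at least 5 CPM, 54.2% at 20 CPM and 45.9% at 50 CPM. Spread shared by replicate number stays open: with a block for the number the share was 56.8%, so the block may bring out small falls that the unblocked fit misses. Residuals of libraries with the same number correlated at only -0.019 to 0.032 between the groups of the HDAC7 line. In the control line, whose libraries enter the same pooled spread, they correlated at 0.111 to 0.413. A fit of the HDAC7 line alone without a block also lowered the share, to 63.2% of 1632 genes. That fit leaves out the control-line spread, so it does not count against this explanation. Induction of HDAC7 stays open as the biological explanation, untested here because no library had HDAC7 induced by other means.

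The list of ATF4 target genes was lower after doxycycline in the HDAC7 line, with a fall of 0.8 in its mean log2 value (the list median was -0.79, and -0.47 without the first untreated HDAC7 library). Doxycycline itself stays open in part: the list mean changed by -0.087 in the control line, with a SD of 0.23 between the 3 numbers. The written rule set a bound of 0.2 on the change alone, and by it this change counts against doxycycline. Adding the SD to the change left the test undecided, and that step was not in the rule. The list median there was -0.318 (camera adjusted p = 2.47e-07) without the second untreated library, -0.279 (adjusted p = 1.12e-05) without the first doxycycline-treated one and 0.274 (adjusted p = 0.000159) without the first untreated one. Those medians come from fits without a block that part a pair of numbers, so they do not tell doxycycline from a difference between numbers. Variation between replicate libraries stays open: the fall was 0.624 times the largest range within a group, which was 1.28 in the untreated control line. Within the HDAC7 line the range was 0.83 untreated and 0.45 with doxycycline. The 2 groups of that line did not overlap: the list mean was 13.42 to 14.25 untreated and 12.84 to 13.29 with doxycycline. In all 4 groups the library numbered 1 was highest and that numbered 2 lowest. Within numbers the change was -0.96, -0.59 and -0.84 in the HDAC7 line and -0.28, 0.16 and -0.14 in the control line, and with a replicate block 26 of 28 members were called lower (camera adjusted p = 3.68e-27, adjusted p = 0.295 with an estimated correlation). The rules for both explanations were set after the values were seen, and HDAC7 induction as a cause was not separately tested.

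The lines differed before induction, with 1061 called genes. Leak of HDAC7 from the uninduced promoter was not settled. HDAC7 was 1.52-fold higher in the untreated HDAC7 line. Among the 1000 genes with the largest line difference a mean of 52.5% ± 5.9 (SD, n = 3) changed in the same direction after induction, in comparisons that shared no library. By the rule set beforehand, which used the mean alone, this share counts against leak. Adding the spread left the test undecided, and that step was chosen after the value was seen. The 3 shares were 46, 54.2 and 57.4%, from divisions that reuse some of the same libraries. Gain or loss of chromosome segments in 1 line also could not be decided, since line differences of adjacent genes correlated at 0.108 over 14512 pairs of genes (genes are not independent replicates), while the doxycycline effect in the HDAC7 line gave 0.119 and the highest of 100 shuffles 0.022. Divergence of the lines during their making stays open as the biological explanation and was not tested.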

How the results depend on the processing

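The alternatives of trimmed-mean scaling, equal totals, quantile normalization, the pseudocounts 10 and 0.5 and leaving out the libraries numbered 1 were chosen after seeing the data; the others were planned. A planned count model (DESeq2) was not run, because the values are not raw counts. Unless a reason is given, the cause was not tested.

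Counts stayed within 1.5 times their reported values with recomputed size factors, the other 3 scalings, both pseudocounts, voom and no filter. With at least 5 CPM in 3 libraries, which tests fewer genes, 461 genes were called in the HDAC7 line and left by the subtraction, 66 in the interaction and 1710 between the doxycycline-treated lines. The stricter FDR of 0.01 gave 348 (the same number after subtraction), 78, 476 between the untreated lines and 1236. A minimum fold of 1.5, also stricter, gave 134 (134 after subtraction), 58, 102 and 361. The replicate block gave 1799 (1799 after subtraction), 439, 2093 and 4314, with a smaller share of rises: 1021 rises and 778 falls in the HDAC7 line, and 321 and 118 in the interaction (73.1% against 96.3%). Only in the control line did the numbers pair the samples by the rule used, and there the block changed no call but that of the MYC target list. In the other comparisons the lowest same-number correlation was between -0.019 and 0.036, and each library correlated best with its own number except those numbered 1 and 3 within the HDAC7 line. A fit of only the groups compared gave 1632 in the HDAC7 line (1031 rises, 601 falls) and 575 between the untreated lines. Without the libraries numbered 1 there were 60 genes in the interaction, 706 between the untreated lines and 1 in the control line.

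Each library was left out in turn, which leaves fewer samples, and a result was recorded only for the libraries of its own comparison. The counts then ran from 336 to 598 in the HDAC7 line and 68 to 168 for the interaction. They ran from 592 to 1103 between the untreated and 1536 to 2995 between the treated lines, and the control line stayed at 0. The subtraction, recorded for all 12 libraries, ran from 336 to 1046. Its counts without 1 control-line library, 655 to 1046, also hold for the HDAC7 line, since the control line had 0 calls. Of 226 named gene values (220 called) 0 reversed under any alternative. Calls were lost by 73 at least once when a library was left out, by 70 at an FDR of 0.01, by 140 with a minimum fold of 1.5 and by 0 with the block. Of 155 list tests (41 called), 41 lost the call with an estimated correlation, 24 with fry (2 gained one), 6 with quantile normalization, 2 with equal totals and 0 with the block (6 gained one), and 13 lost it at least once when a library was left out (26 losses against 56 gains in the same direction, with adjusted p down to 9.59e-09 for MYC targets in the control line). Passes in the direction opposite to the reported fit were not counted as gains. With the block the gains included cholesterol synthesis in the HDAC7 line (0.0479) and pro-B and pre-B genes between the untreated lines (0.0309). Sequencing depth was not estimated, so what it limits was not measured.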

Other observations

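No test of an explanation was made in this part. Called in the interaction were further members of the fixed lists, chosen after their values were seen: the stress gene IER3 (1.88), TNFAIP2 (0.74), the chemokine receptor CCR7 (1.93), the selectin ligand SELPLG (2.78), NFE2 (0.86), the class II gene HLA-DMB (1.45) and HDAC10 (0.44), another deacetylase. BTG2, an antiproliferative p53 target, rose by 1.42 ± 0.23 SE after doxycycline in the HDAC7 line (limma adjusted p = 0.00433), while p53 target genes as a list did not pass there (3 of 23 called up and 0 down, camera adjusted p = 0.643, median -0.04, or 0.024 with equal totals, mean 0.092 and test direction upward).

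Of the 31 lists tested, 16 passed in none of the 5 comparisons as reported, with adjusted p from 0.0598 (NF-kB target genes in the interaction) to 0.991. They included the lists of B-cell lineage, of pro-B and pre-B stages, of p53 targets, of BCL2-family genes and of other deacetylases and sirtuins. Of the 16, 7 passed in at least 1 alternative in the direction of the reported fit and 9 in none. NF-kB target genes passed in the interaction without the second (0.00901) or the third (0.0475) untreated control, the first doxycycline-treated control (0.0235), the first untreated HDAC7 (0.0104) and the first (0.0268) or the second (0.0228) doxycycline-treated HDAC7 library. The lowest adjusted p of these passes was 4.23e-06, for heat shock and unfolded protein genes in the control line without the first untreated library, and cholesterol synthesis genes reached 0.000117 in the interaction without the first doxycycline-treated control library. Along the second principal component the control libraries numbered 1 lay at 27.4 and 36 and the other 4 control libraries between -20.8 and 8.6. Over all 66 pairs of libraries 0.95 to 1.96% of the tested genes had identical values. The 590 genes called higher in the HDAC7 line had a median change of 0.92 there and 0.031 in the control line (quartiles -0.04 to 0.14).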
